A study of Mus musculus with 5 samples.

How the data were processed

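The study measured RNA in single cells of 5 mouse samples with the 10x Genomics 5' chemistry, in which each captured RNA molecule carries a unique molecular identifier (UMI) and each cell a barcode. OT-II cells are CD4 T cells with a transgenic receptor for a peptide of ovalbumin (OVA) presented on MHC class II. They came from the spleen of a naive OT-II mouse by negative selection, and were profiled alone or after overnight coculture with antigen-presenting cancer-associated fibroblasts (apCAFs) sorted from mouse pancreatic tumors of the clones sKPC and rKPC. Cocultures received the vehicle DMSO or OVA. The labels give 5 groups with 1 sample each, so no difference had a replicate check and no test across samples was run.

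The deposited values were UMI counts per gene and barcode, in 2 aggregated matrices, called G and H here, of 32285 genes each. Per the submitters' processing notes the authors used Cell Ranger 6.0.0 and the mouse build mm10, while the matrix headers name cellranger 7.1.0. Whether the aggregation equalised depth between libraries, and whether intronic reads were counted, is not given in the sources used here. If depth was equalised, the totals below are those after it. The labels tie 2 libraries to matrix G, namely the OT-II cells alone and the sKPC coculture with DMSO. They tie 3 to matrix H, namely the sKPC coculture with OVA and the rKPC cocultures with DMSO and with OVA. The barcodes of matrix G carried 3 library suffixes and those of matrix H carried 2, and no source used here maps a suffix to a sample. The 5 libraries were therefore kept unassigned and named Ga, Gb, Gc, Ha and Hb. The suffix numbers would match the labels if the 2 matrix names were exchanged. This was not used, so what the names G and H mean for the groups is open. By a rule fixed before the data were examined, a matrix with more suffixes than its labels list enters no comparison, since its cells can belong to samples not analysed here. The planned comparison of the T cells of the 2 matrices was therefore not made, and the values of Ga, Gb and Gc enter only as values and ranges over unassigned libraries, which describe no group. Such a range can still run from a library of G to a library of H, although the matrices were aggregated separately. The contrasts of the design (coculture against T cells alone, OVA against DMSO, rKPC against sKPC) were not computed either.

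Barcodes were kept with at least 500 UMIs, at least 300 genes and at most 10% mitochondrial UMIs, and when Scrublet, run within each library at an expected rate of 6%, did not mark them. Scrublet marked 19 of 24757 scored barcodes, or 0.0767%, so the doublet caller has not worked on these libraries, and other treatments of doublets were added after seeing the data. The filters left 24620 of 25623 barcodes. Counts were scaled to a common total per cell and log transformed, 2000 variable genes without mitochondrial, ribosomal protein and receptor segment genes were reduced to 30 principal components, and cells were clustered together by Leiden at resolution 1.0 on 15 neighbors. Clusters were named from markers fixed before the data were examined. The scoring thresholds were set afterwards. A class other than T needed at least 3 markers in 20% of cells at 4 times the level of the other cells. T-like needed 6 markers in 50% of cells. A cluster with a median UMI count under 1 part in 3 of its library's and without a marker of its name among its 10 leading genes stayed unnamed. Cluster 12 passed the marker count for macrophages and monocytes but is left unnamed in the text, because its leading genes were of mixed myeloid types. Genes at a high level in it still counted as free RNA in the rankings.

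Within the T-like class, UMIs were summed per library and scaled to the library's T-like total as CPM, the counts-per-million unit applied to UMIs. Values carry exact 95% Poisson intervals, shares exact Clopper-Pearson intervals, and ratios exact binomial intervals. All of these cover counting error only, not differences between cultures or animals. Intervals of UMI counts and ratios treat each UMI as independent and so leave out differences between cells too. A count of 0 is printed as 0 and is to be read as an upper limit of 3 counts. The span of a gene or list is the log2 ratio of its highest to its lowest library among the 5. For single genes in lists 0.5 was added to the counts. Members with at least 100 UMIs in T-like cells counted as measured. A list's median span was placed among 10000 random lists of the same size drawn from the 100 genes nearest each member in total UMIs. The 22 lists fixed in advance were T naive/quiescence, T early TCR response, T costimulation and activation, T inhibitory receptors, T cytokines, Th1, Th2, Th17, Treg, Tfh, T anergy and tolerance, proliferation, ribosome biogenesis and metabolism, interferon response, heat shock and stress, MHC class II, MHC class I, ligands for T cells, suppressive mediators, myCAF, iCAF and mesothelial. Some genes stand in more than 1 list, such as Il2ra, Egr2 and Cd274. Of the interferon list, 16 of 17 members were found among the gene symbols.

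The rule for named genes, also fixed in advance, took up to 4 members of each list with the most UMIs, members with a ratio of at least 2 whose counting interval lay beyond 1.5, the 15 genes with the largest ratio of highest to lowest library within matrix H among genes with at least 100 UMIs, and the 15 genes with the most UMIs in fibroblast-like cells. Since no pools were compared, the ratio used for list members was the span over the 5 libraries. The same ranking within matrix G was run after seeing the data, and only its first 2 genes, Tnnt2 and Lad1, are given, as values per library. Genes named outside this rule, among them Jun, Isg15, Ifit1, Usp18, Klf2, S1pr1, Ccr7, Btg1, Havcr2, Birc5, Tnnt2, Lad1, Gm10076, Gstp1 and Il31ra, were chosen after their values were seen. 1 gene is not reported here. Receptor segments, mitochondrial, ribosomal protein, hemoglobin, Gm and Rik genes were left out of the rankings, as were genes at 10 times the T-like level in another class. For shares of cells with a UMI, each cell was thinned to 1500 UMIs and shallower cells were left out. Erythroid-like cells, thinned alike, were set beside them as a rough gauge of free RNA. To weigh damage as a source of fibroblast-marker barcodes, each was set beside barcodes of its library without such markers at 0.8 to 1.25 times its UMIs. Gene positions come from GENCODE release 21 for mouse (GRCm38), in which 32158 of the 32285 gene identifiers were found.

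The span was computed on simulated Poisson counts for 14117 genes with the libraries' totals. Coverage was checked for the ratio of 1 fixed pair of libraries, Ga over Gb. The intervals of that ratio held the true fold for 95.8% of 13917 unchanged genes, for 95.0% of 100 genes changed 2-fold and for 97.0% of 100 genes changed 4-fold. Since the intervals rest on the same Poisson assumption, this coverage checks the computation only. It does not show that the intervals hold for real counts, whose UMIs can lie together in few cells. The interval of the span, whose pair of libraries is picked by the values, was not checked. The span of unchanged genes had a median of 0.13 on the log2 scale, since the highest and lowest of 5 libraries always differ. Alternatives fixed in advance were stricter and looser cell filters, marked doublets kept, Leiden resolutions 0.5 and 2.0, the matrices clustered separately, classes by the markers of each cell, another denominator, thinning, a mean over cells, and each library left out in turn. Alternatives added after seeing the data were no cell filter, the highest 6% of doublet scores or barcodes over 30000 UMIs left out, classes by cell markers over all barcodes, lists without Il2ra or Cd274, T-like cells without clusters 2 and 9, ratios within matrix H without cells holding a Foxp3 UMI, fibroblast values without very large barcodes, 1 library or mitochondrial UMIs in the total, and the clustering settings, class rule and left-out libraries for the T-like values. Computations used Python 3.11.15 with scanpy 1.11.5, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.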

Results

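Single-cell RNA profiles were collected from naive OT-II CD4 T cells cultured alone or overnight with apCAFs of the pancreatic tumor clones sKPC or rKPC, with DMSO or OVA. The study's design asks how the fibroblasts and the cognate peptide change the state of the T cells. The 5 libraries held 5943 (Ga), 3549 (Gb), 7136 (Gc), 4630 (Ha) and 4365 (Hb) barcodes, with 50382852, 27339447, 61279131, 37545788 and 35071753 UMIs in the same order. The median barcode held 8471, 7658, 8247, 8149 and 8058 UMIs. Matrix G held 3 libraries against 2 in its labels and matrix H held 2 against 3, and none could be tied to a culture condition. Each library is therefore given as its own value, without a group, and no difference between libraries is read as an effect of coculture, clone or peptide. Between 2 and 14 barcode sequences were shared by any pair of libraries, so no library was a copy of another.

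Most kept barcodes were T-like, a share that depends on the filter and does not measure the make-up of the cultures. T-like cells, defined by Cd3d, Cd3e, Trac, Lck and related T cell genes, made up 21779 of 24620 kept barcodes, or 88.5% (88.1 to 88.9). Their share was 89.5% in Ga, 88.0% in Gb, 89.4% in Gc, 86.1% in Ha and 88.4% in Hb. Clusters 2 and 9, 10.3% of T-like cells (9.68% in Gc to 11.0% in Ha), held a UMI of Cd4 in 5.61% and 6.99% of cells and of the gamma-delta TCR gene Trdc in 84.1% and 91.7%. B-like cells (60, 0.244%) and erythroid-like cells (38, 0.154%) were few. Another 99 barcodes (0.402%) were NK-like, but this name rested on the setting: no cluster bore it with the stricter filter or with no cell filter, and with marked doublets kept it went to a cluster of 423 barcodes with other leading genes. Cluster 12 (142 barcodes, 0.577%) was led by the myeloid gene Lyz2 with the neutrophil gene S100a8, the granulocyte precursor genes Elane, Prtn3 and Ctsg and the basophil gene Mcpt8, and is left without a cell type. The naming rule gave cluster 12 the name macrophage/monocyte-like, which is set aside here. No cluster was named fibroblast-like, mesothelial-like, epithelial-like, endothelial-like, mural-like, neutrophil-like or dendritic cell-like, which sets no limit on cells of these types inside other clusters. The CD8 T-like name rested on Cd8a and Cd8b1 alone but needed at least 3 markers, so no cluster could receive it. At resolution 2.0, 46 kept barcodes (0.187%) formed a fibroblast-like cluster, and 7 (0.0284%) were fibroblast-like by their own markers. Barcodes in other unnamed clusters were 9.20% of Ga, 10.3% of Gb, 9.29% of Gc, 12.5% of Ha and 10.2% of Hb, and most lay in a cluster with a median of 970 UMIs. When each barcode was classed by its own markers, the T-like share was 97.9% of kept barcodes.

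Genes induced by engagement of the T cell receptor (TCR) spanned a wider range than any other list in T-like cells as summed CPM. The early TCR response list summed to 1322 CPM in Ga (1311 to 1332), 329 in Gb (321 to 336), 1205 in Gc (1196 to 1214), 386 in Ha (379 to 392) and 325 in Hb (319 to 331). This is a span of 2.02 on the log2 scale (1.99 to 2.05), and of 2.17 without clusters 2 and 9, a choice made after seeing the data. Of its 17 measured members 14 spanned at least 2-fold, and the list's median span exceeded that of all 10000 random lists (percentile 100). By the median over members the cytokine list was wider, with 3.14 against 2.85. The orphan nuclear receptor Nr4a1 (ENSMUSG00000023034, chromosome 15, 101254269 to 101274795, GRCm38), an immediate target of TCR signaling, stood at 134 CPM in Ga, 2.75 in Gb, 113 in Gc, 2.11 in Ha and 1.23 in Hb. Irf4 (ENSMUSG00000021356, chromosome 13, 30749226 to 30766976), whose level follows TCR signal strength, stood at 162, 2.58, 135, 1.39 and 0.888 CPM in the same order.

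Nuclear receptor, zinc finger and growth genes of the early TCR response list spanned wide ranges too. In Ga, Gb, Gc, Ha and Hb, Nr4a3 stood at 120, 3.93, 107, 4.56 and 2.33 CPM, and the activation marker Cd69 at 226, 26.4, 204, 19.5 and 20.3. Egr1 stood at 69.7, 3.85, 57.9, 3.72 and 4.20, and Myc, a driver of growth, at 41.0, 5.65, 34.9, 5.97 and 6.10. The AP-1 genes ran apart: Fos stood at 4.86, 1.31, 4.49, 1.13 and 1.65 CPM, Jun at 27.7, 29.9, 30.1, 30.4 and 29.7, and Junb at 148, 92.3, 169, 127 and 101. With cells thinned, the spans of Irf4 and Egr1 moved by over 1.5 times, to 6.85 from 7.51 and to 5.85 from 4.23 on the log2 scale. Without Hb, the library with the lowest values, the span of Nr4a1 was 5.99 in place of 6.78 and that of Irf4 6.87. The T-like class was made of several clusters, of which cluster 6 was the largest in Ga and Gc and cluster 5 in Gb, Ha and Hb, while clusters 0 and 4 lay mostly in Ga and Gc. The T-like CPM of a library is thus an average over clusters held in different proportions.

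Receptors and cytokines of activated T cells also varied. The costimulation and activation list stood at 714, 357, 636, 381 and 352 CPM in Ga, Gb, Gc, Ha and Hb, with 5 of 9 members spanning at least 2-fold (Il2ra, Tnfrsf4, Tnfrsf9, Cd200 and Tfrc). Il2ra (ENSMUSG00000026770, chromosome 2, 11642807 to 11693193), the high-affinity chain of the interleukin-2 receptor, stood at 228, 8.65, 201, 10.7 and 7.35. Its span of 4.96 became 5.67 when the highest 6% of doublet scores were left out. Cd40lg, the ligand of CD40, ranged from 95.6 in Gc to 146 in Hb. The cytokine list stood at 228, 114, 229, 118 and 112, with 9 of 11 measured members at 2-fold or more, among them Tnf (22.8, 2.17, 18.4, 2.86 and 2.39), Lta (24.6, 3.61, 21.3, 2.77 and 3.002) and Il2 (6.92, 0.656, 12.2, 1.33 and 1.38). The chemokine Ccl4 stood at 31.0, 0.369, 33.9, 1.67 and 0.490 CPM, and its span of 6.52 became 7.35 with marked doublets kept, 7.28 without the highest doublet scores, 8.07 without clusters 2 and 9 and 5.78 with classes by cell markers. The span of Lta, 3.15, became 2.56 in thinned cells, and that of Il2, 4.22, became 3.20 without Gb and 3.40 without Gc. After thinning, a UMI of Il2 was held by 0.259% of T-like cells in Ga, 0.172% in Gb, 0.458% in Gc, 0.0513% in Ha and 0.243% in Hb. These shares did not follow the CPM values, as Ga and Hb were close. Ifng was low, at 1.01, 0.901, 1.65, 0.577 and 0.735 CPM, a log2 span of 1.49 (0.81 to 2.29) at 20 to 94 UMIs, highest in Gc and lowest in Ha.

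**Figure D1:**
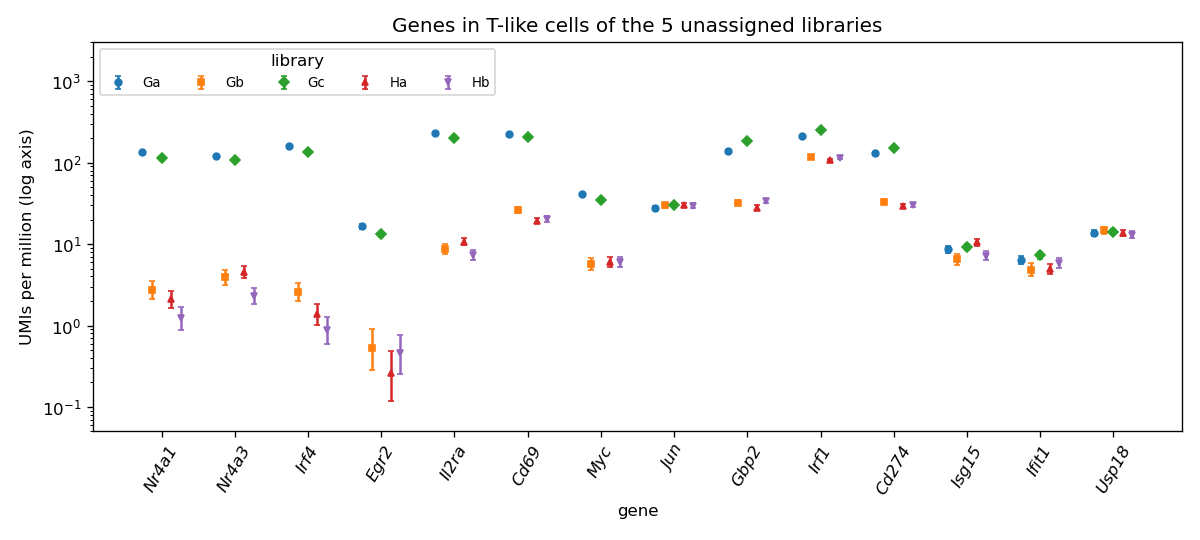
CPM (log axis) of 14 genes in the T-like cells of the 5 unassigned libraries, one point per library with its exact 95% Poisson interval. Nr4a1 ranges from 1.23 (Hb) to 134 (Ga), whereas Jun lies between 27.7 and 30.4 and Usp18 between 13.1 and 14.7.

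Genes of the interferon response spanned 1.21 on the log2 scale (1.19 to 1.23), with the list at 1736 CPM in Ga, 871 in Gb, 1969 in Gc, 853 in Ha and 907 in Hb. Members at 2-fold or more included the transcription factor gene Irf1 and the GTPase genes Igtp, Gbp2 and Gbp4, known best as targets of interferon gamma. Gbp2 (ENSMUSG00000028270, chromosome 3, 142620602 to 142638008) stood at 139, 32.3, 186, 28.1 and 33.9 CPM in Ga, Gb, Gc, Ha and Hb. Isg15, Ifit1 and Usp18, well known from type I interferon, ranged from 6.47 to 10.5, from 4.84 to 7.25 and from 13.1 to 14.7. The checkpoint ligand Cd274 stood at 133, 33.3, 152, 29.2 and 30.4. The percentile among random lists was 100 for the interferon list and 99.78 for the inhibitory receptors, which stood at 312, 173, 327, 202 and 149 with Lag3, Havcr2 and Cd274 at 2-fold or more. Without Cd274, a choice made after seeing the data, the inhibitory receptors stood at 179, 139.7, 175, 172 and 119, and their span of 1.14 became 0.60.

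Growth genes and naive-state genes differed less than the TCR-response genes as sums, although their median members spanned more than those of random lists. The ribosome biogenesis and metabolism list stood at 2938, 1844, 2664, 1910 and 1888 CPM in Ga, Gb, Gc, Ha and Hb, a span of 0.67, with 10 of 17 members at 2-fold or more and a percentile of 100. Among them the amino acid transporter gene Slc7a5 stood at 53.5, 10.5, 45.1, 9.61 and 9.93. The naive/quiescence list spanned 0.17 and stood at 10774, 12109, 11540, 11876 and 11946, while its median member spanned 0.49 (percentile 99.96) and members ran in different directions. Its members Klf2 and S1pr1, which keep naive T cells recirculating, stood at 490.1, 614, 461, 641 and 666 and at 442, 592, 473, 589.8 and 624. The lymph node homing receptor Ccr7 stood at 306, 178, 295, 199.99 and 187, and Btg1, a brake on proliferation, at 918, 818, 1142, 780.3 and 825. With Ga left out the naive list spanned 0.069. Proliferation genes spanned 0.18, from 156 in Gb to 177 in Hb, with Mki67, Top2a, Cdk1 and Birc5 at 2-fold or more at low counts.

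**Figure D2:**
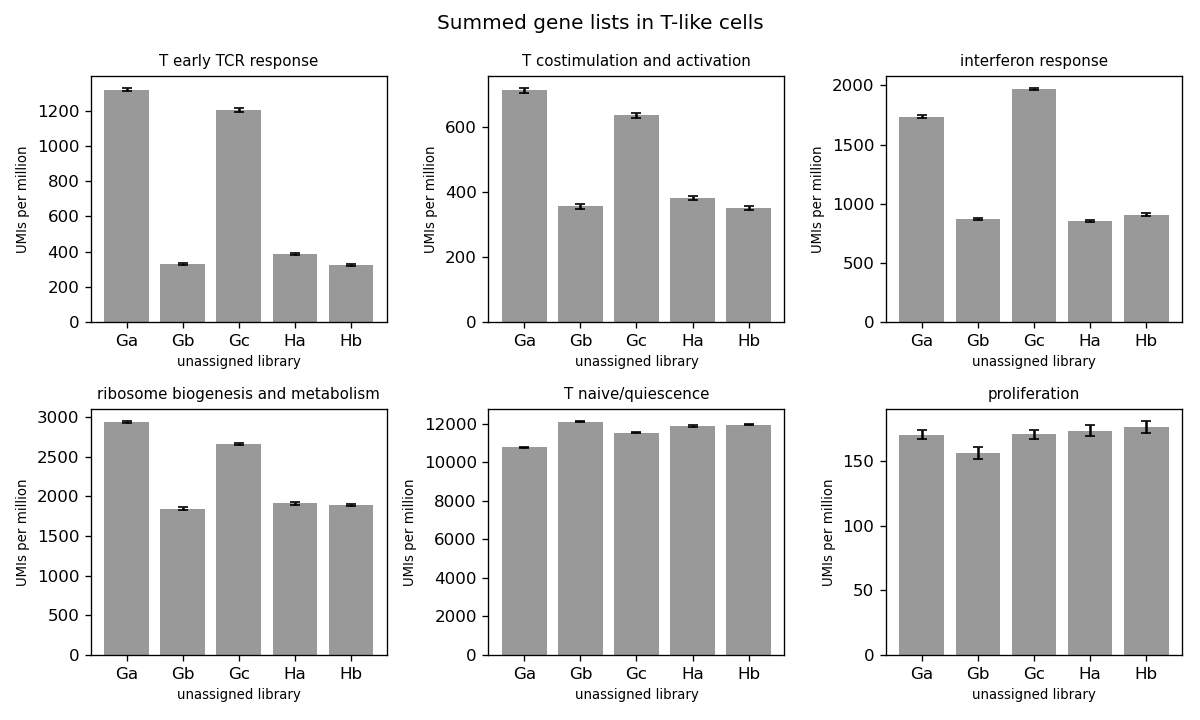
Summed CPM of 6 gene lists (y axes from 0) in the T-like cells of the 5 unassigned libraries (x axes), as bars with exact 95% Poisson intervals as error bars. The early TCR response bars range from 325 to 1322 and the naive/quiescence bars from 10774 to 12109.

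Among the lists of T cell lineages, the Treg list spanned 0.74, from 425 CPM in Hb to 710.1 in Ga, with Foxp3, Il2ra, Lrrc32 and Gpr83 at 2-fold or more (percentile 100). Without Il2ra, a choice made after seeing the data, it spanned 0.35 and stood at 482, 492, 473, 532 and 418 in Ga, Gb, Gc, Ha and Hb, highest in Ha. The Th1, Th2, Th17 and Tfh lists spanned 0.30, 0.25, 0.29 and 0.23 as sums, with percentiles of 93.95, 78.95, 98.87 and 96.05 by their median members. Foxp3 stood at 11.2, 5.29, 8.71, 9.78 and 3.77 CPM in Ga, Gb, Gc, Ha and Hb, and Ctla4 at 61.3, 53.7, 64.2, 82.7 and 42.2. The anergy and tolerance list spanned 0.16 as a sum, with Egr2, Egr3, Izumo1r and Ndrg1 at 2-fold or more (percentile 100). Within T-like cells the heat shock and stress list spanned 0.38 (Ddit3 and Atf3 at 2-fold or more, percentile 99.98), MHC class I 0.25, MHC class II 0.47, ligands for T cells 0.92, suppressive mediators 0.43, myCAF 0.09 and iCAF 0.88. The iCAF value was mostly Ly6c1, which T cells also express, at 270.5, 492, 305, 469 and 503 CPM. Mesothelial genes had no member with 100 UMIs and stood between 0.490 and 0.901.

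Cells with UMIs of TCR-response genes were compared at equal depth. After thinning to 1500 UMIs, 1056 of 5028 T-like cells in Ga (19.9% to 22.2%), 2.34% in Gb (1.82 to 2.96), 19.1% in Gc (18.1 to 20.1), 2.46% in Ha (1.999 to 2.999) and 1.43% in Hb (1.07 to 1.87) held a UMI of Nr4a1, Nr4a2, Nr4a3, Egr1, Egr2, Egr3, Irf4 or Il2ra. The unthinned shares were 37.5%, 8.91%, 34.4%, 10.5% and 8.02%, at median depths of 8840, 8024, 8595, 8449 and 8305 UMIs. Thinning left out 28, 15, 44, 27 and 13 cells. Erythroid-like cells, which should lack these genes, held such a UMI in 3 of 33 cells (9.09%, 1.92 to 24.3) after thinning and in 18.2% before, at a median of 10630 UMIs. These cells were pooled over libraries, with 13 of the 38 erythroid-like cells from Ga and 9 from Gc, and are too few to give the background of any 1 library. Doublets with T cells among them are not excluded, as the doublet caller has not worked. Trac was held by 42.1% of erythroid-like cells against 100% of B-like cells, so their background can differ from that of other barcodes. In a test added after seeing the data, the UMIs of the 8 genes were spread at random over the thinned T-like cells of their library 100 times. Cells with at least 3 of the 8 genes numbered 435 in Ga against 225 to 291 in the spreadings, 421 in Gc against 188 to 257, and 3, 3 and 1 in Gb, Ha and Hb against at most 1, 1 and 0.

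Within matrix H, Il1rl1, Foxp3 and Tnfrsf9 were higher in Ha, and Esm1 and Pdzrn3 in Hb. Among 9848 ranked genes, with 489 left out as free RNA, the 15 largest ratios were 10 genes higher in Ha (Il1rl1, Pard3, Foxp3, Atp6v0d2, Tnfrsf9, Slco4a1, Lrrc32, Adamts3, Gpr55 and Atcay) and 5 higher in Hb (Pdzrn3, Sh3rf2, Esm1, Dnm3 and Gabrr2). Il1rl1, the receptor for interleukin-33, had 124 UMIs in Ha and 22 in Hb, a log2 ratio of 2.38 (1.75 to 3.13). Foxp3, the master regulator of regulatory T cells, had 339 and 123, a log2 ratio of 1.37 (1.07 to 1.69), and Tnfrsf9 had 310 and 119, a log2 ratio of 1.29 (0.99 to 1.61). After thinning, 36 of 3898 T-like cells in Ha (0.924%, 0.648 to 1.28) and 20 of 3704 in Hb (0.540%, 0.330 to 0.833) held a UMI of Foxp3. Before thinning these shares were 2.31% and 1.59%. The interval of the Foxp3 ratio treats its UMIs as independent, although they lay in few cells. In T-like cells without a UMI of Foxp3, a choice made after seeing the data, the log2 ratio was 0.37 (-0.10 to 0.85) for Tnfrsf9 and 0.0093 (-1.03 to 1.06) for Lrrc32, and Il1rl1 had 19 UMIs in Ha and 0 in Hb. Each of these values rests on a single library.

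The main clustering named no fibroblast-like class. RNA of fibroblast markers such as Col1a1, Col3a1 and Sparc was present among all barcodes, at 11.1 CPM in Ga (10.2 to 12.0), 96.5 in Gb (92.8 to 100.2), 11.3 in Gc (10.5 to 12.2), 0.906 in Ha (0.627 to 1.27) and 9.01 in Hb (8.04 to 10.1). In Gb, 1 barcode held 1246 of the 2637 marker UMIs, and without it that library stood at 51.2 CPM (48.5 to 53.9). In T-like cells of the same libraries the same markers stood at 2.43, 2.25, 1.70, 0.693 and 1.47. When every barcode was classed by its own markers without a cell filter, a setting added after seeing the data, 198 of 25623 were fibroblast-like, 50 in Ga, 63 in Gb, 51 in Gc, 0 in Ha and 34 in Hb. Clustering with no cell filter, also added after seeing the data, gave an unnamed cluster of 965 of 25604 barcodes (3.77%, 3.54 to 4.01) with Cald1, Sparc, Tagln and Col1a1 leading, which held all 198. Of the 965, 421 held a fibroblast marker, 544 held none and 435 were T-marker barcodes, and the 75 from Ha held no UMI of these markers. Of the 198, 191 held over 10% mitochondrial UMIs, against 189 of 24392 T-marker barcodes. The median fibroblast-marker barcode held 683.5 UMIs, 49.0% of them mitochondrial.

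The 15 genes with the most UMIs in these 198 barcodes were mt-Co3, Malat1, mt-Co1, mt-Atp6, mt-Co2, mt-Nd1, mt-Nd4, mt-Cytb, Actb, mt-Nd2, Rpl41, Fth1, Gm42418, S100a6 and mt-Nd3. The contractile myofibroblast (myCAF) genes summed to 2924 CPM (2815 to 3036) against 55.8 in T-like cells, with 1085 UMIs of Tpm1, 864 of Tagln and 488 of Acta2. The inflammatory (iCAF) list summed to 390.4 (351 to 433), against 385 in T-like cells, which was mostly Ly6c1, and its member Cxcl12 had 170 UMIs (183 CPM) against 0.0102 CPM in T-like cells. The mesothelial list summed to 128 CPM (106 to 154) against 0.694 in T-like cells, but the 57 UMIs of its leading gene Upk1b came from 1 barcode and the 41 of Wt1 from 3. Suppressive mediators summed to 1387 (1312 to 1465) against 124, mostly the prostaglandin synthase gene Ptgs2 (879 UMIs), and MHC class I to 1434 (1358 to 1513) against 4020.5. Ligands for T cells summed to 252 (221 to 287) against 229.9, and included 76 UMIs of Pvr and 40 of Nectin2. In Gb, 4 barcodes with over 100000 UMIs held 84.6% of all UMIs in the set. Without them the myCAF list stood at 2514 CPM, with 69 UMIs of Tpm1 (485 CPM in place of 1170.1), 107 of Tagln and 90 of Acta2, and Cxcl12 had 14 UMIs (98.3 CPM). Pvr then had 0 UMIs, Nectin2 2, Upk1b 0 and Wt1 1. The mesothelial list stood at 35.1 CPM, suppressive mediators at 414 with 2 UMIs of Ptgs2, and MHC class I at 2317. Of the UMIs in the remaining barcodes 48.6% were mitochondrial, against 2.01% in T-like cells. With mitochondrial UMIs out of the total, a choice made after seeing the data, MHC class I stood there at 4511 (4037 to 5025) against 4103 in T-like cells, the myCAF list at 4893 against 56.9, the iCAF list at 902 (698 to 1148) against 393, ligands for T cells at 369 (243 to 537) against 235 and suppressive mediators at 806 against 126.

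MHC class II genes, whose products present peptides such as OVA to CD4 T cells, were far lower in the fibroblast-marker barcodes than in B-like cells. The list held 69 UMIs, or 74.4 CPM (57.9 to 94.2), against 144 in T-like cells (142 to 146), 195 in barcodes classed as T-like by the same rule, 4553 in B-like cells (4421 to 4687) and 2591 in the myeloid cluster 12 (2547 to 2635). Most of the T-like value was the protease gene Ctss, at 108 CPM. In fibroblast-marker barcodes 45 of the 69 UMIs were of Ifi30, of which 2 lay outside the 4 large barcodes. The presenting chains H2-Aa, H2-Ab1 and H2-Eb1 and the invariant chain Cd74, a subset chosen after the values were seen, held 13 UMIs in fibroblast-marker barcodes, or 14.0 CPM (7.46 to 24.0), against 6.70 in T-like and 4029 in B-like cells. Of the 13 UMIs, 8 were of Cd74, 3 of H2-Ab1, 2 of H2-Aa and 0 of H2-Eb1. Outside the 4 large barcodes Cd74 had 7, H2-Aa 2 and H2-Ab1 1. Without the 4 large barcodes these 4 genes stood at 70.2 (33.7 to 129) and the list at 112 (64.2 to 182), and without Gb at 100.8 (48.4 to 185) and 151. With mitochondrial UMIs also out of the total, they stood outside the 4 large barcodes at 137 (65.5 to 251) against 6.83 in T-like cells, and the list at 219 (125 to 355) against 147. Without Hb the 4 genes stood at 8.86. The cluster of 965 barcodes found with no cell filter, which held all the fibroblast-marker barcodes, held 108 UMIs of the 4 genes, or 45.6 CPM. Most of these UMIs thus lay in barcodes of that cluster not classed as fibroblast-like. A level above that of T-like cells was therefore not particular to the barcodes classed as fibroblast-like. Some of the others in that cluster held a fibroblast marker, and their cell type was not tested. By library the 4 genes stood in the cluster at 157, 11.7, 25.2, 18.8 and 147 CPM in Ga, Gb, Gc, Ha and Hb. In the 46 barcodes of the resolution 2.0 cluster, whose median was 7750 UMIs, the 4 genes held 7 UMIs, or 5.43 CPM (2.18 to 11.2), and the list stood at 76.8 (62.4 to 93.5). Without 5 barcodes of that cluster with over 100000 UMIs the 4 genes stood at 15.02 (4.09 to 38.5) and the list at 150.2 (107 to 204).

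**Figure D3:**
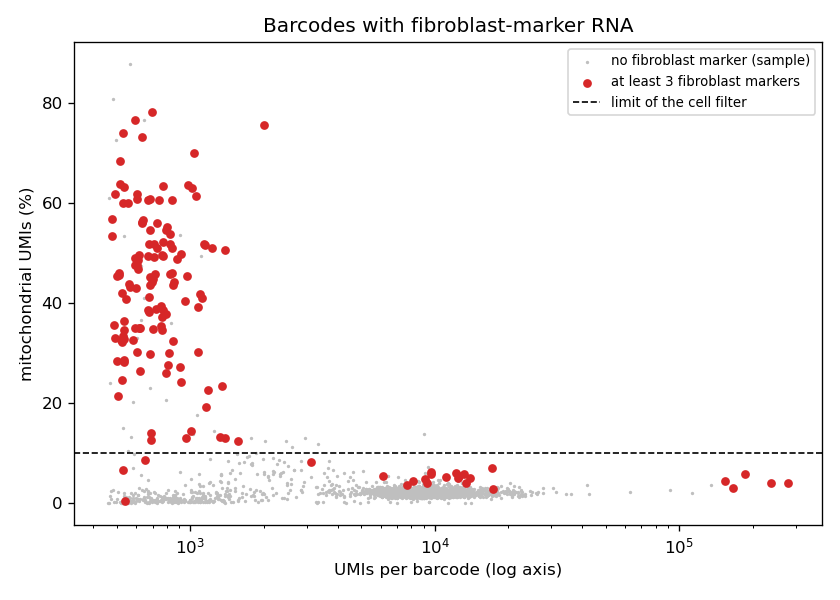
UMIs per barcode (x axis, log) against the percentage of mitochondrial UMIs (y axis) for the 149 barcodes with at least 3 fibroblast markers (red) and a random sample of barcodes with none (grey), all libraries together. The dashed line is the 10% limit of the cell filter, and 124 of the 149 red points lie above it.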

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

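All tests in this part were chosen after the result was seen. Among all barcodes, 198 carried at least 2 fibroblast markers and more of these than of any other type, a signal in data that the class shares and T cell values do not use. They numbered 50 in Ga, 63 in Gb, 51 in Gc, 0 in Ha and 34 in Hb, and 191 of them exceeded the mitochondrial limit while 7 were kept.

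One technical explanation is free fibroblast RNA spread over all barcodes in proportion to their UMIs. Over the 5 libraries, 149 barcodes held at least 3 fibroblast markers, against 102 to 146 in 100 random spreadings of the same UMIs, which leaves this open. After that result was seen the libraries were taken apart: the 104 such barcodes of Ga, Gc and Hb (43, 40 and 21) exceeded the highest of their spreadings (4, 6 and 4), which argues against free RNA there, while the 45 of Gb lay below its 98 to 144 and decide nothing, as 1 barcode held 1246 of that library's 2637 marker UMIs. A second explanation, damaged fibroblasts removed by the mitochondrial limit, stays open. Of the 149, 83.2% (76.2 to 88.8) lay over the limit, against an average of 14.0% of barcodes without such markers from the same library with a similar number of UMIs, but lying over it is part of the pattern itself and so decides nothing. The culture conditions of the design stay open as untested, because no library could be tied to one.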

How the results depend on the processing

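The Trdc-cluster, mitochondrial-total, clustering, class-rule and left-out-library settings for the T-like values, no cell filter, the 2 added doublet treatments and classes over all barcodes were chosen after the result was seen. The T-like share, 88.5%, was 94.6% with the stricter filter, 87.6% with the looser, 86.5% with marked doublets kept, 89.3% at resolution 0.5, 89.4% with matrices clustered separately, 86.0% with no cell filter, 89.1% without barcodes over 30000 UMIs, 97.9% by cell markers and 95.2% by cell markers over all barcodes. With 1 library left out at a time it was 88.1% to 89.0%. The fibroblast-like share, 0%, was 0.187% at resolution 2.0, 0.0284% by cell markers and 0.773% by cell markers over all barcodes, and 0% with any library left out. With no cell filter it was 0%, but 3.77% of barcodes lay in an unnamed cluster led by fibroblast genes, of which 421 of 965 held a fibroblast marker. In thinned cells the log2 spans were 1.89 for the early TCR list, 1.28 for interferon, 0.58 for ribosome biogenesis and 0.16 for the naive list, and as a mean over cells 1.90, 1.30, 0.55 and 0.14. The early TCR span was 2.07 with marked doublets kept, 2.13 without the highest doublet scores and 1.95 by cell markers. Without clusters 2 and 9 the spans were 2.17, 1.23, 0.73 and 0.19. The stricter filter gave 0.64 for ribosome biogenesis and 0.15 for the naive list, and the other denominator 0.16 for the latter. Leaving out 1 library gave 1.89 to 2.02 (early TCR), 1.03 to 1.21 (interferon), 0.53 to 0.67 (ribosome biogenesis) and 0.069 (without Ga) to 0.17 (naive). The cause was not tested. Of 272 values of 21 named genes over 13 settings, 236 stayed within their counting interval, 36 did not, and 8 moved by over 1.5 times (Irf4, Egr1, Lta, Il2ra and 4 of Ccl4). The MHC class II list had a value only where fibroblast-like barcodes existed: 76.8 CPM in 46 barcodes at resolution 2.0 (150.2 without barcodes over 100000 UMIs), 68.6 in 7 by cell markers (789 without Gb) and 74.4 in 198 over all barcodes (112 without barcodes over 100000 UMIs, 218.7 with mitochondrial UMIs also out of the total, and 69.7 to 151 with 1 library left out). The value of 789 rests on 1 barcode of Gc and 1 of Hb, since 5 of the 7 lay in Gb. Alternatives of the comparison between matrices, TMM factors, equal library weights and other minimum counts among them, were not run, because that comparison was not made. No paired analysis was possible because each group had 1 sample and no library carried a group.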

Other observations

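The tests, single genes and subsets of lists in this part were chosen after the result was seen. The thinning of cells was planned, and the lists and cell type markers were fixed in advance.

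Marker RNA of other cell types was uneven over the 5 libraries, and for neutrophil and B cell markers its source, cells or free RNA, was not tested. Neutrophil markers, S100a8 and S100a9 among them, stood over all barcodes at 86.2 CPM in Ga, 102 in Gb, 48.0 in Gc, 2.88 in Ha and 111 in Hb, and fibroblast markers at 11.1, 96.5, 11.3, 0.906 and 9.01. B cell markers stood at 14.4, 23.8, 20.9, 49.4 and 31.8. Cd8a stayed between 0.169 and 0.260 CPM in T-like cells, Cd4 between 165 and 257, and Trdc, which marks clusters 2 and 9 of that class, between 83.9 and 126. Trac, which encodes the constant region of the TCR alpha chain, stood at 7629, 6734, 3851, 7323 and 6789, lowest in Gc, whereas Trbc1 lay between 517 and 584. Gc was also lowest for Gm10076 (281, 247, 58.9, 309 and 232), Gstp1 (49.0, 55.4, 17.5, 62.6 and 56.1) and Il31ra (19.7, 13.8, 6.70, 29.3 and 22.5).

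Sums of the early TCR list fell into 2 separate ranges over the 5 libraries. They stood at 1322 (Ga) and 1205 (Gc) CPM on one side and at 329 (Gb), 386 (Ha) and 325 (Hb) on the other, with no group assigned to either. Fosb, Jun and Tnfaip3 did not divide so: Fosb stood at 1.29, 2.29, 2.12, 0.808 and 1.13 CPM in Ga, Gb, Gc, Ha and Hb, highest in Gb, Jun at 27.7, 29.9, 30.1, 30.4 and 29.7, and Tnfaip3 at 90.5, 85.1, 95.5, 117 and 83.4. Tnnt2, a cardiac troponin gene outside the lists, had 725, 0, 745, 1 and 0 UMIs in T-like cells of Ga, Gb, Gc, Ha and Hb. Lad1, its neighbor on chromosome 1 (135818598 to 135833342, with Tnnt2 at 135836354 to 135852260), had 1532, 1, 1556, 6 and 1.

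The span of the early TCR list was weighed against 2 technical explanations. The greater weight of deep cells in the sums does not account for it. With all cells at 1500 UMIs the span was 1.89 (1.81 to 1.96), against 2.02 before. Thinning leaves the expected share of a gene within each cell unchanged, so it cannot decide on other effects of depth. Stress from handling or dissociation, which raises AP-1 genes, stays open: Fos, Fosb, Jun and Junb together spanned 0.71 (0.65 to 0.77), above a 1.5-fold span but below the square root of the list's own fold, and these 4 genes belong to the list. OVA, clone and coculture, which the design names, stay open as untested, since no library could be tied to a condition.

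The span of the interferon list was weighed against 2 explanations. A response to type I interferon alone is argued against by 9 members known best from it (Isg15, Ifit1, Ifit3, Irf7, Oasl1, Rsad2, Usp18, Bst2 and Ifi27l2a), which together spanned 0.38 (0.34 to 0.43), against 1.52 (1.499 to 1.543) for the other 7. A response only of cells in which TCR-response UMIs were found is argued against. In T-like cells without a UMI of the 8 genes the list spanned 1.38 (1.36 to 1.40), at 2031, 853, 2216, 851 and 896 CPM in Ga, Gb, Gc, Ha and Hb. Cells with such UMIs stood at 1326, 1032, 1582, 868 and 1014. A cell without such a UMI can still have responded through its TCR, so a response confined to TCR-engaged cells stays open. Cd69 stood at 29.2, 21.6, 34.5, 15.4 and 17.6 CPM in the cells without such UMIs. The culture conditions stay open as untested, and Ifng itself was at or below 1.65 CPM in T-like cells, highest in Gc and lowest in Ha like the list.

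Ribosome biogenesis genes divided differently from the interferon list. In T-like cells without TCR-response UMIs they stood at 1847, 1811, 1792, 1868 and 1879 CPM, and in cells with them at 4463, 2150.0, 4034, 2227 and 1980.0. Cells with more UMIs are more often counted as having one, so this division is not free of depth.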
